A study of Mus musculus with 6 samples.

How the data were processed

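Messenger RNA was sequenced from hearts of 6 mice aged 32 weeks, 3 ApoE-/- littermates (libraries 1, 2 and 3) and 3 ApoE-/- Timp3-/- mice (libraries 4, 5 and 6). RNA was extracted with Trizol and made into standard Illumina libraries, per the labels. The labels number the libraries 1 to 6 without a number shared between the groups, so the fit had no block. They call the controls littermates, and beyond that nothing says how the samples relate, so p-values measure the spread between these samples.

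The authors deposited 1 Cufflinks transcript file per library, with the FPKM and the read coverage of each transcript, per the file attributes. TopHat, Bowtie, Cufflinks and the genome build NCBIM37 are named per the submitters' processing notes. Their versions and settings, the read length and whether strand was used are not given in the sources used here. Each file held between 94574 and 94603 reference transcripts, 94670 over all files and 94445 in all 6, and transcripts assembled in that library alone, 70603 together. Each library's FPKM were normalized by themselves. The files hold no reads per gene, so no count test was run. Reads of a gene and of a transcript overlapping it on either strand cannot be told apart here.

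Reference transcripts were given to genes by transcript ID (82348), by the gene ID in the file (5266) or by exon overlap of at least 50% (6232), and 824 were given to none. A later reference annotation served for identifiers and symbols alone; every coordinate is from the files, in NCBIM37. Assembled transcripts of at least 300 nt were given to a gene where at least 50% of the exonic bases of either overlapped the other's, which took 39245 of them. This step was set after the files were seen, since assembled transcripts held 34.0% to 39.6% of the aligned bases. Between 74.8% and 81.2% of the bases of a library went to a gene. A gene's value was the sum of its transcripts' FPKM. Of 36757 genes, 33922 had a symbol, and 159 were left out because a transcript of theirs was absent from a file. The mitochondrial genome was not analysed here. The pseudogenes Gm13340 and Gm13341, which resemble mitochondrial sequence, held 3.99% to 6.38% and 1.09% to 1.66% of the bases.

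Depth was judged from coverage times transcript length, 654 to 1339 aligned megabases per library. Reads per gene are not known, so no counting interval is given. An FPKM of exactly 0 can be a failed estimate, since Mrpl44, a gene that most cells use, was listed at 0 in 2 control libraries. For genes at 0 in a library, each library's value is therefore given, and no fold against a group at 0.

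The following was fixed before the data were examined: groups, tests, filters, gene lists and the rule for named genes. Genes entered the test with a mean deposited FPKM of at least 1 over the 6 libraries and a longest transcript of at least 300 nt. FPKM were scaled between libraries by the median of ratios (factors 0.898 to 1.17), and log2(scaled FPKM + 1) was tested two-sided with limma 3.58.1 in R 4.3.3, with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. Means ± SD are of scaled FPKM, and values of single libraries are as deposited. Exact permutation p are given for the targeted gene. With 3 against 3 libraries the smallest they can reach is 0.1, so they cannot pass 0.05. The same limma fit was made for single transcripts with a mean FPKM of at least 1. Genes within 20 Mb of Timp3 were compared with all others by a two-sided Fisher's exact test at an unadjusted p under 0.01.

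The 35 gene lists were written by hand. Lists with at least 5 tested genes were compared with all other genes by limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Sampling and cell content were covered by lists for red blood cells, atrial cells, adipocytes, skeletal muscle, smooth muscle, fibroblasts, endothelium, macrophages, lymphocytes, neutrophils, cell cycle, clock, immediate early, heat shock and sex genes. Some lists share genes, for example Col1a1, Lum and Dcn in the matrix and fibroblast lists, Fabp4 in the endothelial and fatty acid uptake lists, Apln and Adm in the apelin and hypoxia lists, and Notch3 in the Notch and smooth muscle lists.

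The named genes were Timp3, Apoe, Syn3, Apln and Aplnr, up to 10 genes past the threshold in each direction without overlap between groups, the 4 members with the smallest p of each list described, and the 5 genes near Timp3 with the smallest p. Members were named for the 18 lists that passed, for the apelin list and for the clock list, the last chosen after its values were seen. Mrpl44, Nppa, Zfp30, Blvrb, Mrps12 and the Hadhb transcript fell outside the rule and were named after their values were seen. Some genes that the rule takes are not reported here.

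The alternatives changed 1 choice at a time: no further scaling, quantile normalization, scaling to a fixed total, pseudocounts of 0.1 and 10, no filter, a filter at 5 FPKM, no length filter, the transcript with the highest mean, limma without trend, with robust estimation or with library weights, voom on reads estimated from coverage (with a placeholder read length of 50), and leaving out each library. Alternatives chosen after seeing the data were a stricter assignment of assembled transcripts, reference transcripts alone, coverage in place of FPKM, removal of the trend with transcript length in each library (lowess, span 0.3) and leaving out genes listed at 0 in any library.

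The test was tried on simulated data for this comparison, with 11221 genes and 200 changed. It recovered 69% of the genes changed 2-fold and 89% of those changed 4-fold, and 10 of the 168 genes called were unchanged. The adjustment is stricter where fewer genes change, so these shares hold for 200 changed genes only. They are not the recovery in the data, where 5 of 11385 genes passed. There Col3a1, at a log2 difference of -0.98, had an adjusted p of 0.18 by limma. A list shifted by -0.40 was found at -0.41, and 1 of 30 lists was called. The simulated noise was drawn independently for each gene, and changes were put into FPKM + 1. In the data the estimated correlation between genes was 0.14 for matrix genes and 0.96 for red cell genes. The simulation therefore could not show how often correlated genes make a list pass. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and plotting.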

Results

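The series measured messenger RNA by sequencing in hearts of 32-week-old mice. Apolipoprotein E-deficient mice (ApoE-/-), which develop high blood cholesterol and atherosclerosis, were the littermate controls, with 3 libraries numbered 1, 2 and 3. Mice lacking both apolipoprotein E and tissue inhibitor of metalloproteinases 3 (ApoE-/- Timp3-/-, below the double mutants) gave the other 3 libraries, numbered 4, 5 and 6. Timp3 encodes a secreted protein that inhibits matrix-degrading and membrane-shedding proteases. The values were FPKM (fragments per kilobase of transcript, relative to all mapped fragments of the library). The coverage given with them added up to 654, 1339 and 827 aligned megabases in libraries 1, 2 and 3 and to 910, 732 and 683 in libraries 4, 5 and 6. After the filter on low values, 11385 genes were tested. The title of the series names an axis of TIMP3 and apelin, heart metabolism and mortality, so the target, apelin and its receptor, metabolic genes and the cell types of the heart were compared between the genotypes.

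The targeted gene came first, because its level checks the labels. Timp3 (chromosome 10, 85763117 to 85812251, build NCBIM37) was lower in the double mutants but was not lost. Its single transcript was listed at an FPKM of 52.1, 38.0 and 36.3 in libraries 1, 2 and 3 and of 20.2, 28.0 and 29.6 in libraries 4, 5 and 6. After scaling, the mean was 40.6 ± 3.62 in the controls and 26.7 ± 6.12 in the double mutants (SD, n = 3 each), a log2 difference of -0.61 with a 95% interval of -1.05 to -0.17. All 3 double mutants lay below all 3 controls, yet the gene did not pass limma's test over all genes (adjusted p = 0.29). The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Which part of Timp3 the mutation removes is not given in the sources used here, so reads from the rest of the gene could not check the labels. The genotypes below are those of the labels. Syn3, the synapsin gene that holds Timp3 within an intron, was listed at 0 in all 6 libraries. Apoe, targeted in both groups, had a scaled FPKM of 2.97 ± 0.651 in the controls and 2.52 ± 0.819 in the double mutants (SD, n = 3 each; log2 difference -0.19, adjusted p = 0.76 by limma). The Apoe difference ran from -0.36 without library 4 to -0.04 without library 6, with -0.08 without library 1 and -0.32 without library 2.

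Apelin and its receptor were both lower in the double mutants, although neither passed the test over all genes. Apln, which encodes the peptide hormone apelin (chromosome X, 45378323 to 45388030), had a scaled FPKM of 2.55 ± 0.846 in the controls and 0.90 ± 0.180 in the double mutants (SD, n = 3 each; log2 difference -0.88 ± 0.20 SE). Aplnr, the apelin receptor gene (chromosome 2, 84976517 to 84980079), was at 11.6 ± 1.37 against 3.71 ± 2.07 (log2 difference -1.51 ± 0.29 SE). For both genes, all 3 double mutants lay below all 3 controls. The adjusted p by limma was 0.24 for Apln and 0.23 for Aplnr. With libraries weighted by their spread Aplnr passed, at a log2 difference of -1.75 and an adjusted p of 0.037, the lowest over its settings; the highest was 0.36, and 0.57 with a library left out. In the list of apelin, angiotensin and endothelin signalling, 14 of 22 genes were tested, with a median log2 difference of -0.24 and 9 genes below 0. Apln and Aplnr passed downward when adjusted over the list alone, and 3 genes had an unadjusted p under 0.05. Npr1, a natriuretic peptide receptor, was at 3.85 ± 0.520 against 2.84 ± 0.101, and Adm, encoding the vasodilator adrenomedullin, at 2.40 ± 0.593 against 3.29 ± 0.454. The list as a whole did not pass camera, limma's test of a list against all other genes (adjusted p = 0.052, and 0.40 with an estimated correlation, unadjusted 0.086). It did not pass fry, limma's test of a list by itself, either (adjusted p = 0.11), although its unadjusted fry p of 0.0040 was the lowest of all lists. By camera the list passed without library 5, with a median of -0.15, and under 5 other settings. The median was -0.14 without library 2 (adjusted p = 0.12 by camera) and -0.15 without library 6 (adjusted p = 0.13).

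**Figure D1:**
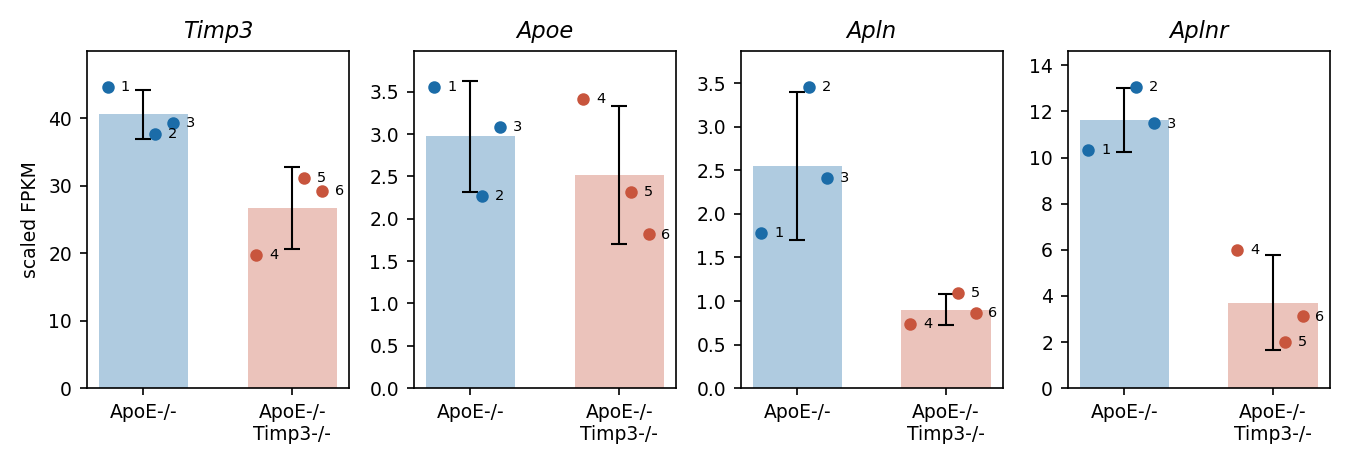
Scaled FPKM (vertical axes, starting at 0) of Timp3, Apoe, Apln and Aplnr in the 3 ApoE-/- and the 3 ApoE-/- Timp3-/- libraries. Points are libraries with their numbers, bars are group means and error bars are 1 SD. For Timp3, Apln and Aplnr all 3 double mutants lie below all 3 controls, while the groups overlap for Apoe.

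Over all genes, 5 of 11385 passed limma's test at an adjusted p under 0.05, with 3 higher and 2 lower in the double mutants. All 5 were listed at 0 in every library of one genotype. Mapkapk5, a stress-activated protein kinase (chromosome 5, 121975047 to 121995914), was listed at an FPKM of 12.1, 14.1 and 19.1 in libraries 1, 2 and 3 and at 0 in libraries 4, 5 and 6 (adjusted p = 0.0043). Cfhr2, a complement factor H-related gene (chromosome 1, 141701945 to 141755276), was listed at 4.72, 2.22 and 2.97 in libraries 1, 2 and 3 and at 0 in the others (adjusted p = 0.027). In the other direction, Wdfy1, an endosomal WD-repeat protein gene (chromosome 1, 79698837 to 79772718), was listed at 0 in the controls and at 4.40, 7.34 and 5.49 in libraries 4, 5 and 6. Patz1, encoding a zinc-finger transcription regulator (chromosome 11, 3188877 to 3209086), was listed at 0 in the controls and at 5.04, 3.47 and 7.37 in the double mutants. Trim12a, a tripartite-motif gene (chromosome 7, 111448408 to 111463980), was listed at 0 in the controls and at 2.60, 2.54 and 2.72 in the double mutants. The adjusted p was 0.0092 for each of Wdfy1, Patz1 and Trim12a. Transcripts outside the gene overlapped Trim12a, Wdfy1 and, at a mean FPKM under 1, Mapkapk5 by position. Those over Trim12a had a mean FPKM of 5.62 in the libraries where it was at 0 and of 6.44 in the others, and without strand such reads cannot be told apart. The overlap with Wdfy1 came from Mrpl44, which was itself listed at 0 in libraries 1 and 3 and at 38.9 in library 2.

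A listed 0 was not proof of absent RNA in these files. Mrpl44, a mitochondrial ribosomal protein gene that most cells use and whose end overlaps Wdfy1 by position, was listed at 0 in libraries 1 and 3 and at 30.7 to 38.9 in the others. Among the tested genes, 300 were listed at 0 in at least 1 library. With these 300 left out, an alternative chosen after the data were seen, 0 genes passed. When libraries were weighted by their spread, library 3 carried a weight of 2.98 and library 4 of 0.35, and 104 genes passed. With the strongest transcript of each gene 4 passed, and 0 of them were among the 5. The count was 3 without library 1, 11 without library 2 and 10 without library 4. Of the called genes, Mapkapk5 kept its call whichever library was left out. Patz1 and Wdfy1 lost theirs without library 1 (adjusted p = 0.057 each by limma), Wdfy1 also without library 6 (0.055) and Trim12a without library 5 (0.060). Cfhr2 kept its call without library 2 and lost it without library 1 (0.057), 3 (0.12), 4 (0.071), 5 (0.12) or 6 (0.13). Over the other settings the adjusted p of these 5 genes ran from 1.1e-04 to 0.53.

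Below the threshold, many genes had a small unadjusted p or did not overlap between the groups. At an unadjusted p under 0.05 stood 1387 genes, 12.2% of those tested, with 792 higher and 595 lower in the double mutants. The groups did not overlap in 2185 genes, 19.2% of those tested, where chance gives 10%. The median SD between replicates was 0.20 on the log2 scale, against a median absolute difference between genotypes of 0.16.

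Extracellular matrix genes were lower together in the double mutants. Col3a1, a fibrillar collagen, was at a scaled FPKM of 63.3 ± 9.52 in the controls and 31.4 ± 2.05 in the double mutants (SD, n = 3 each, as for all means below). Col4a1, a basement membrane collagen, was at 33.6 ± 8.90 against 13.9 ± 2.41, Fbn1, which encodes the microfibril protein fibrillin, at 7.94 ± 1.51 against 3.03 ± 0.837, and Loxl1, a crosslinking enzyme of elastic fibres, at 9.002 ± 1.63 against 4.39 ± 0.853. Their log2 differences were -0.98, -1.20, -1.16 and -0.89. Of the 45 genes in the list of extracellular matrix and fibrosis, 41 were tested, 35 had a difference below 0 and the median was -0.44. The list fell by camera (adjusted p = 6.3e-12, and 0.40 with an estimated correlation). Adjusted over the list alone, 20 genes passed downward and 1 upward. Over all genes tested, 0 of them passed limma's test, with 22 lower and 1 higher at an unadjusted p under 0.05. With the estimated correlation its unadjusted p of 0.027 was the lowest of all lists. The mean of the list lay above 0 in libraries 1, 2 and 3 (deviations of 0.32, 0.24 and 0.06) and below 0 in libraries 4, 5 and 6 (-0.21, -0.18 and -0.23).

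Proteases of the matrix and fibroblast markers shifted the same way by camera. Among metalloproteinases and their inhibitors other than Timp3, 21 of 34 genes were tested, 19 had a difference below 0 and the list fell with a median of -0.24 (adjusted p = 0.0027, and 0.40 with an estimated correlation). Adamts5, an aggrecan-degrading protease, was at 2.16 ± 0.157 against 1.26 ± 0.264, Mmp14, a membrane-bound collagenase, at 3.68 ± 0.421 against 2.38 ± 0.565, and Adam15 at 11.7 ± 1.57 against 8.83 ± 1.51. Adamts1 was at 2.92 ± 0.738 against 3.87 ± 0.201, in the other direction. By limma's test 0 of these genes passed when adjusted over the list alone, with 3 lower and 0 higher at an unadjusted p under 0.05. Without library 1 the list lost its call, with a median of -0.16. Apart from single libraries, 3 of 20 settings ended the call, the estimated correlation and fry among them. Of the fibroblast markers, 14 of 15 were tested, and the list fell with a median of -0.31 (adjusted p = 0.0027, and 0.40 with an estimated correlation). The mean of this list overlapped between the groups. It deviated by 0.27, 0.21 and -0.06 in libraries 1, 2 and 3 and by -0.24, 0.0009 and -0.18 in libraries 4, 5 and 6. Cd248, a surface marker of stromal cells, was at 4.08 ± 1.09 against 1.73 ± 0.210 and Col1a1, the main fibrillar collagen gene, at 15.4 ± 3.34 against 8.37 ± 1.32, and these 2 genes passed when adjusted over the list alone. Mfap5, a microfibril gene, was at 14.4 ± 6.12 against 7.05 ± 1.99. Wif1, a secreted inhibitor of Wnt signalling, went the other way, from 1.71 ± 1.00 to 3.81 ± 0.802.

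Endothelial genes were lower as a list in the double mutants, though the mean of the list overlapped between the genotypes. Cdh5, the cadherin of endothelial junctions, was at 29.2 ± 4.93 in the controls and 18.0 ± 0.515 in the double mutants. Kdr, a receptor for vascular endothelial growth factor, was at 17.1 ± 1.81 against 11.4 ± 1.03, Tek, the angiopoietin receptor, at 8.03 ± 0.150 against 5.66 ± 0.328, and Mmrn2, an endothelial matrix gene, at 6.81 ± 0.472 against 5.16 ± 0.426. All 22 endothelial markers were tested, 19 had a difference below 0, and the list fell with a median of -0.31 (adjusted p = 2.1e-04 by camera, and 0.40 with an estimated correlation). Cdh5, Tek and Kdr were the 3 that passed when adjusted over the list alone. The mean of the markers was not low in every double mutant: it deviated by 0.10 in library 4, by -0.22 in library 5 and by -0.27 in library 6. In control libraries 1, 2 and 3 it deviated by 0.025, 0.30 and 0.057, so library 4 lay above controls 1 and 3. The median was -0.16 without library 2 and -0.19 without library 6. Red cell genes, given below, were highest in library 4.

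Mural cell, Notch and hypoxia lists passed more narrowly, and the mean of each list overlapped between the genotypes. For smooth muscle and pericytes, double mutant library 4 (0.021) lay above control library 1 (0.0084). For Notch and hypoxia, double mutant library 5 (0.063 and 0.057) lay above control library 1 (-0.094 and -0.0093). Over all runs other than the main one, the smooth muscle and pericyte list passed in 10 of 26. The Notch list passed in 9 of 25 and the hypoxia list in 15 of 26. In the list of smooth muscle cells and pericytes, 13 of 15 genes were tested, with a median of -0.23 (adjusted p = 0.048, and 0.40 with an estimated correlation). Its members moved in opposite directions. The pericyte-enriched genes Notch3 (4.59 ± 0.294 against 3.19 ± 0.155) and Cspg4 (2.20 ± 0.371 against 1.25 ± 0.0195) and the myosin kinase gene Mylk (3.45 ± 0.125 against 2.32 ± 0.260) were lower, while the smooth muscle actin gene Acta2 was higher, at 26.2 ± 4.14 against 41.1 ± 9.73. There were 4 genes that passed downward when adjusted over the list alone, and Acta2 passed upward. Of the Notch signalling genes, 13 of 14 were tested, and the list fell with a median of -0.18 (adjusted p = 0.049, and 0.40 with an estimated correlation). Besides Notch3, the Notch ligand Dll4 was at 6.99 ± 1.22 against 5.42 ± 0.780, Heyl, a Notch target, at 3.098 ± 0.481 against 2.38 ± 0.493, and the endothelial receptor Notch4 at 3.20 ± 1.11 against 2.26 ± 0.270. Adjusted over the list alone, 0 genes passed limma's test, with 1 lower at an unadjusted p under 0.05. In the hypoxia response list, 18 of 20 genes were tested, with a median of -0.15 (adjusted p = 0.043, and 0.40 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, was at 12.1 ± 1.17 against 6.13 ± 0.611, and with Apln it passed downward when adjusted over the list alone. P4ha1, a collagen prolyl hydroxylase, was at 8.27 ± 0.892 against 5.98 ± 0.414 and Slc2a1, a glucose transporter, at 4.13 ± 0.978 against 2.98 ± 0.336. The smooth muscle list lost its call without library 2 (median -0.26), 3 (-0.04), 5 (-0.11) or 6 (-0.22), the hypoxia list without library 2 (-0.08), 3 (-0.05), 4 (-0.13) or 6 (-0.07). The smooth muscle median was -0.38 without library 1. The Notch list kept its call without library 5 (-0.28) and lost it without library 1 (-0.14), 2 (-0.14), 3 (-0.18), 4 (-0.25) or 6 (-0.11).

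Genes of fatty acid oxidation were slightly higher in the double mutants. Acadl, a dehydrogenase for long-chain fatty acids, was at 477 ± 35.6 in the controls and 662 ± 89.5 in the double mutants. Decr1, which handles unsaturated fatty acids, was at 57.5 ± 5.30 against 77.5 ± 8.98, Eci2, an enoyl-CoA isomerase, at 37.9 ± 5.20 against 50.2 ± 3.26, and Mlycd, which removes the oxidation inhibitor malonyl-CoA, at 19.8 ± 1.43 against 26.3 ± 2.69. In this list 28 of 29 genes were tested, 23 had a difference above 0, and the list rose with a median of 0.22 (adjusted p = 3.3e-04 by camera, and 0.40 with an estimated correlation). Adjusted over the list alone, 0 genes passed limma's test, with 6 higher at an unadjusted p under 0.05. The median was 0.13 without library 4, and quantile normalization ended the call, with a median of 0.09. Regulators and targets of the PPAR and PGC-1 pathway rose as a list as well, with 24 of 26 genes tested and a median of 0.19 (adjusted p = 0.0080, and 0.40 with an estimated correlation). The uncoupling protein genes Ucp3 (15.3 ± 8.88 against 33.3 ± 6.25) and Ucp2 (20.03 ± 6.83 against 36.1 ± 11.8) were higher. Pparg, the adipogenic receptor of the family, was lower, at 3.19 ± 0.432 against 2.00 ± 0.466. Of these, 0 passed limma's test adjusted over the list alone, with 5 higher and 1 lower at an unadjusted p under 0.05, and the list lost its call without library 5, with a median of 0.15.

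Genes of fatty acid and sterol synthesis were lower. Srebf2, the regulator of cholesterol synthesis, was at 3.17 ± 0.120 against 2.15 ± 0.0425, Elovl5, a fatty acid elongase, at 9.50 ± 1.29 against 6.77 ± 0.522, and Cyp51, a sterol demethylase, at 2.22 ± 0.107 against 1.53 ± 0.203. Acacb, whose product makes malonyl-CoA at mitochondria, was at 26.0 ± 0.972 against 33.4 ± 5.71. Of 33 genes 21 were tested, 19 had a difference below 0, and the list fell with a median of -0.30 (adjusted p = 0.0069, and 0.40 with an estimated correlation). Adjusted over the list alone, 0 genes passed limma's test, with 3 lower at an unadjusted p under 0.05. This list followed library 1, where its mean deviated by 0.71 and that of adipocyte markers by 2.25. Without library 1 the median was -0.04 and the call was lost, and without library 4 the median was -0.20. Apart from single libraries, 7 of 20 settings ended the call, the estimated correlation and fry among them. For Srebf2 and Cyp51 the direction turned when only reference transcripts, or only the strongest transcript, were used. Other metabolic lists did not pass camera. The median was 0.09 in the tricarboxylic acid cycle (22 genes, adjusted p = 0.13), 0.05 in the nuclear-encoded respiratory chain (73 genes, adjusted p = 0.27), 0.02 in glucose uptake and glycolysis (32 genes, adjusted p = 0.87) and -0.03 in fatty acid uptake and lipid droplets (30 genes, adjusted p = 0.87). The sign of the first 3 turned under other scalings, and the first median was 0.05 without library 1 and 0.04 without library 4. The tricarboxylic acid cycle passed upward with voom (0.10, adjusted p = 0.048) and with the length trend removed (0.11, adjusted p = 0.031). Without library 1 or 4 the median turned to -0.02 for glycolysis in each case and to 0.06 and 0.04 for fatty acid uptake. The respiratory chain passed upward without library 2 (0.16) or 6 (0.16) and was below 0 without library 1 (-0.07) or 4 (-0.09), and under quantile normalization it passed downward (-0.12, adjusted p = 6.8e-04), so its direction is unsettled.

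The mean of the interferon response genes was low in libraries 5 and 6 but not in library 4, although the 4 members named here were low in all 3. Ifi44, an interferon-induced gene, was at 2.61 ± 0.470 against 0.752 ± 0.108, Ifit2 at 3.82 ± 1.01 against 1.99 ± 0.241 and Oas1a, an antiviral enzyme gene, at 1.42 ± 0.0237 against 0.647 ± 0.186. Irf7, a transcription factor of the interferon response, was listed at 4.25, 7.18 and 4.56 in libraries 1, 2 and 3, at 0 in libraries 4 and 5 and at 2.21 in library 6. Of 35 genes 32 were tested, 23 had a difference below 0, and the list fell with a median of -0.31 (adjusted p = 5.9e-05 by camera, and 0.46 with an estimated correlation). Ifi44 and Irf7 passed downward when adjusted over the list alone. The mean of the list deviated by 0.12, 0.22 and 0.19 in libraries 1, 2 and 3, by 0.25 in library 4, above all controls, by -0.54 in library 5 and by -0.24 in library 6. The median was -0.52 without library 4 and -0.14 without library 5. A stricter filter on low values ended the call. Macrophage markers did not pass, with a median of -0.05 over 22 genes (adjusted p = 0.92). They stood apart in library 1, by 0.83, and without that library they were higher in the double mutants, with a median of 0.32 that passed camera. Genes of TNF and NF-kB responses had a median of -0.16 over 17 genes (adjusted p = 0.25), and of -0.09 without library 5.

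Genes of the working and stressed heart muscle shifted in different directions. Myh7, the slow myosin heavy chain that rises in stressed hearts, was at 76.6 ± 3.28 in the controls and 125 ± 19.8 in the double mutants, and it was the 1 gene of its list that passed when adjusted over the list alone. Other members were lower. Rcan1, a target of calcineurin, was at 13.9 ± 5.59 against 7.93 ± 0.576, Ankrd23, a stretch-responsive gene, at 237 ± 151 against 80.8 ± 18.3, and Mybpc2 at 3.62 ± 1.73 against 2.03 ± 0.771. The list of cardiac stress and hypertrophy had 18 of 21 genes tested and fell with a median of -0.29 (adjusted p = 0.033, and 0.58 with an estimated correlation). Its mean deviated by 0.67 in library 2. Without library 2 the median was -0.09 and the call was lost, as it was without library 6 (-0.25), and without library 1 the median was -0.46. Apart from single libraries, 5 of 20 settings ended the call, the estimated correlation and fry among them. Genes of calcium handling and ion channels did not pass (34 genes, median 0.01, mean 0.05, adjusted p = 0.99), and camera set this list on the lower side while its median and mean were above 0. Its median was -0.11 without library 2 and changed sign under other scalings. Immediate early genes rose as a list, with 13 of 21 genes tested and a median of 0.25 (adjusted p = 0.0078, and 0.40 with an estimated correlation). Nr4a1, a nuclear receptor induced within minutes of a stimulus, was at 2.37 ± 1.31 against 12.1 ± 6.02 and Zfp36, an RNA-decay factor, at 8.03 ± 1.70 against 12.6 ± 1.01, and both passed when adjusted over the list alone. Atf3 was at 1.90 ± 0.708 against 4.14 ± 1.52 and Fosl2 at 2.88 ± 0.496 against 3.98 ± 0.771. The list lost its call without library 1 (median 0.15) or 4 (0.23).

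Cytosolic ribosomal protein genes rose as a list, with 44 of 45 tested, 39 above 0 and a median of 0.25 (adjusted p = 6.2e-06 by camera, and 0.49 with an estimated correlation). Rpl15 was at 24.5 ± 0.954 against 38.4 ± 3.59, Rpl5 at 27.2 ± 1.35 against 39.4 ± 2.37 and Rps23 at 14.1 ± 2.66 against 20.6 ± 1.21, while Rpl30 was lower, at 21.7 ± 1.95 against 12.0 ± 2.67. Rpl15, Rpl5 and Rpl30 passed when adjusted over the list alone. These genes have many processed copies in the genome that can share their reads, so their values are uncertain. The mean of the list was highest in library 4, by 0.53, and lowest in library 3, by -0.27, as were red cell genes (3.61 and -2.10), and the median was 0.11 without library 4, 0.38 without library 6 and 0.12 under quantile normalization, where the list still passed. The ribosomal list mean of double mutant library 6 (-0.12) lay below that of control library 2 (0.006), so the genotypes overlapped. Across genes, which are not independent replicates, the fold change correlated with transcript length by a Spearman rho of -0.20. Within libraries 1 to 6 the deviation of a gene from its mean correlated with length at 0.34, -0.24, 0.31, -0.47, 0.09 and 0.15, the strongest in library 4. With the trend on transcript length removed in each library, an alternative chosen after the data were seen, the median was 0.20 for ribosomal protein genes, -0.41 for matrix genes and 0.18 for fatty acid oxidation, and all 3 lists passed camera at its preset correlation. Without this removal and with an estimated correlation their adjusted p was 0.49, 0.40 and 0.40.

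Markers of cells and tissues beside the ventricle differed between libraries. Red blood cell genes rose as a list (7 of 11 tested, median 2.68, adjusted p = 3.1e-04, and 0.40 with an estimated correlation), with the mean of the list highest in library 4, by 3.61, and lowest in library 3, by -2.10. The globin gene Hba-a2 was listed at an FPKM of 9506 in library 4 and at 78.0 to 900.0 in the other libraries, and took 1.15% of the bases in library 4. The log2 differences of Hba-a1, Hba-a2 and Hbb-bt, near-identical to sister genes that can share their reads, were 2.82, 2.85 and 2.91. Without library 4 the list's median was 1.49, and the list passed whichever library was left out. Of the red cell genes, 0 adjusted over the list alone passed limma's test, with 5 higher at an unadjusted p under 0.05. Atrial markers rose as a list (14 of 15 tested, median 0.86, adjusted p = 0.033, and 0.58 with an estimated correlation) but did not follow the genotypes. Myl7, the atrial myosin light chain, was listed at 409, 2.09 and 1.21 in libraries 1, 2 and 3 and at 13.4, 173 and 229 in libraries 4, 5 and 6. Bmp10, an atrial growth factor, was listed at 0.477, 0.0217 and 0.167 in the controls and at 0, 10.1 and 32.5 in the double mutants. Sbk2 was at 3.13 ± 3.75 against 6.08 ± 3.57 and Stard10 at 16.1 ± 12.9 against 23.3 ± 8.90. Of them, 0 adjusted over the list alone passed limma's test, and 0 had an unadjusted p under 0.05. The atrial median was 1.49 without library 1, and the call was lost without library 2 (0.52), 3 (0.55), 5 (0.69) or 6 (0.49).

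Adipocyte markers fell as a list (13 of 15 tested, median -0.56, adjusted p = 0.033, and 0.58 with an estimated correlation), through library 1. Ucp1, the uncoupling protein of brown fat, was listed at 31.6, 0.0398 and 0 in libraries 1, 2 and 3 and at 0, 0.0348 and 0 in libraries 4, 5 and 6. Aqp7, a glycerol channel, was at 5.52 ± 0.281 against 3.61 ± 0.538, Thrsp, a lipogenic gene, at 15.8 ± 8.58 against 8.40 ± 3.27 and Adig, an adipogenic gene, at 3.68 ± 3.91 against 1.123 ± 1.499. By limma's test 0 passed when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05. Without library 1 the median turned to 0.14. The call was also lost without library 4 (-0.39) or 6 (-0.42), and the median was -1.28, -1.15 and -1.31 without library 2, 3 and 5. Skeletal muscle genes rose as a list (6 of 14 tested, median 0.36, adjusted p = 0.0069, and 0.40 with an estimated correlation), from low levels. The fast myosin genes Myh2 (1.22 ± 0.306 against 2.53 ± 0.825) and Myh4 (1.65 ± 0.232 against 2.48 ± 0.222) and the calcium-storage gene Casq1 (2.70 ± 0.152 against 3.67 ± 0.382) were higher. Mylpf, a fast myosin light chain, was listed at 4.74, 0 and 5.99 in the controls and at 9.22, 4.49 and 3.74 in the double mutants. Adjusted over the list alone, 0 passed limma's test, with 3 higher at an unadjusted p under 0.05, and the list lost its call without library 2 (0.23) or 4 (0.33). The sign of Myh4 turned with reference transcripts alone.

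**Figure D2:**
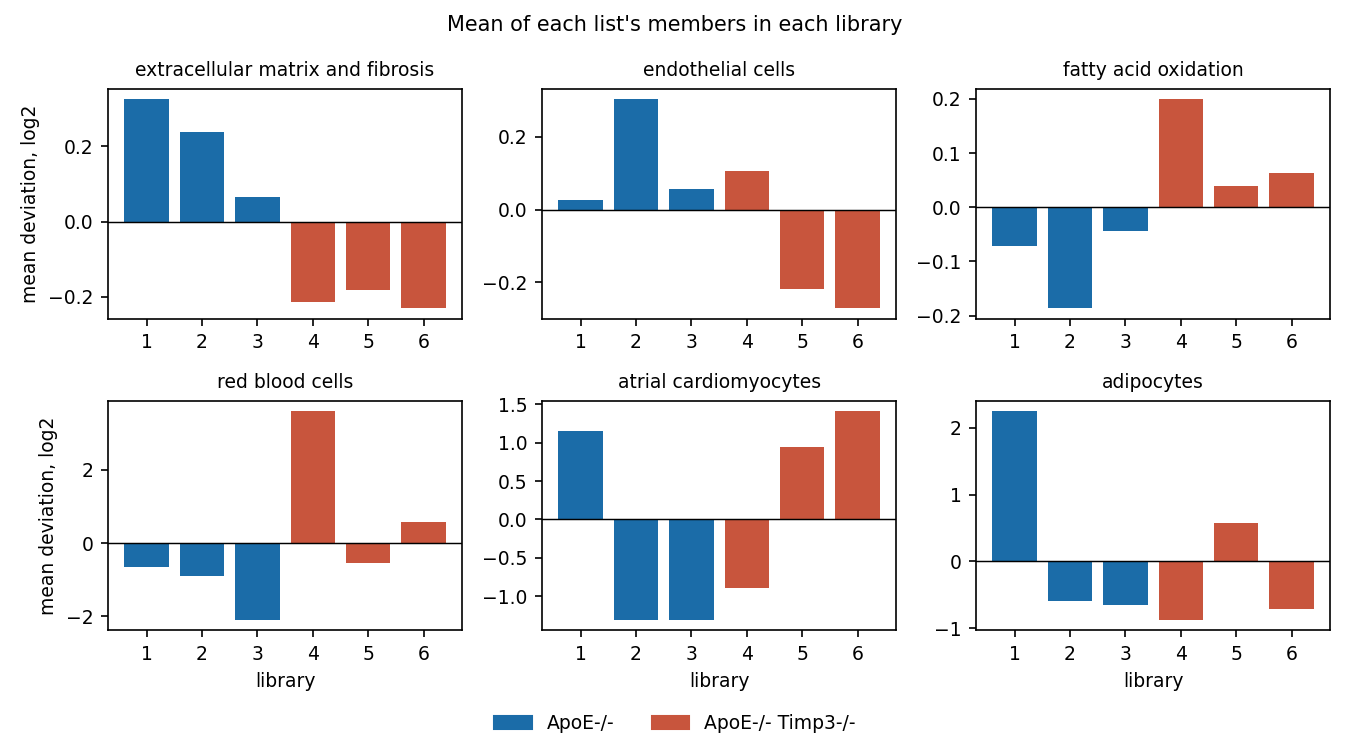
Mean deviation of 6 gene lists from their mean over all libraries (vertical axes, log2 of scaled FPKM + 1) in libraries 1 to 6; bars are means over the list's genes in 1 library, coloured by genotype. Matrix genes are above 0 in all 3 controls and below 0 in all 3 double mutants, while red cell markers stand out in library 4 (3.61), adipocyte markers in library 1 (2.25) and atrial markers in libraries 1, 5 and 6 (1.15, 0.94 and 1.41).

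In all, 18 of the 30 lists with at least 5 tested genes passed camera at an adjusted p under 0.05, 7 upward and 11 downward. With a correlation estimated for each list 0 passed, and 2 had an unadjusted p under 0.05, those of matrix genes and of metalloproteinases. By fry, limma's test of a list by itself, 0 passed and 7 had an unadjusted p under 0.05. The other lists that did not pass had a median of 0.13 for heat shock proteins (12 genes, adjusted p = 0.15), -0.02 for unfolded protein and oxidative stress (30 genes, adjusted p = 0.84; mean 0.04, on the upper side by camera) and -0.04 for the epidermal growth factor family (5 genes, adjusted p = 0.86; mean 0.02). The heat shock median was 0.04 without library 1, 0.06 without library 4, 0.28 without library 2 and 0.25 without library 6, it passed with no filter on low values (0.14, adjusted p = 0.021), and its sign turned under quantile normalization and under scaling to a fixed total. Near 0, the unfolded protein median turned in 3 of the 6 fits with a library left out. It was 0.03 without library 2 and 0.02 without library 5. The growth factor median turned to 0.03 without library 1. Fewer than 5 genes were tested for T and B lymphocytes (4 genes, median 0.20), neutrophils (2 genes, median 0.19) and cell cycle (4 genes, median -0.06; mean 0.02), and 0 for the mitochondrial genome. The median of all genes was -0.01 after scaling. Rescaling to a fixed total outside the mitochondrial genome moved it to -0.16, and the medians above are relative to the first.

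**Figure D3:**
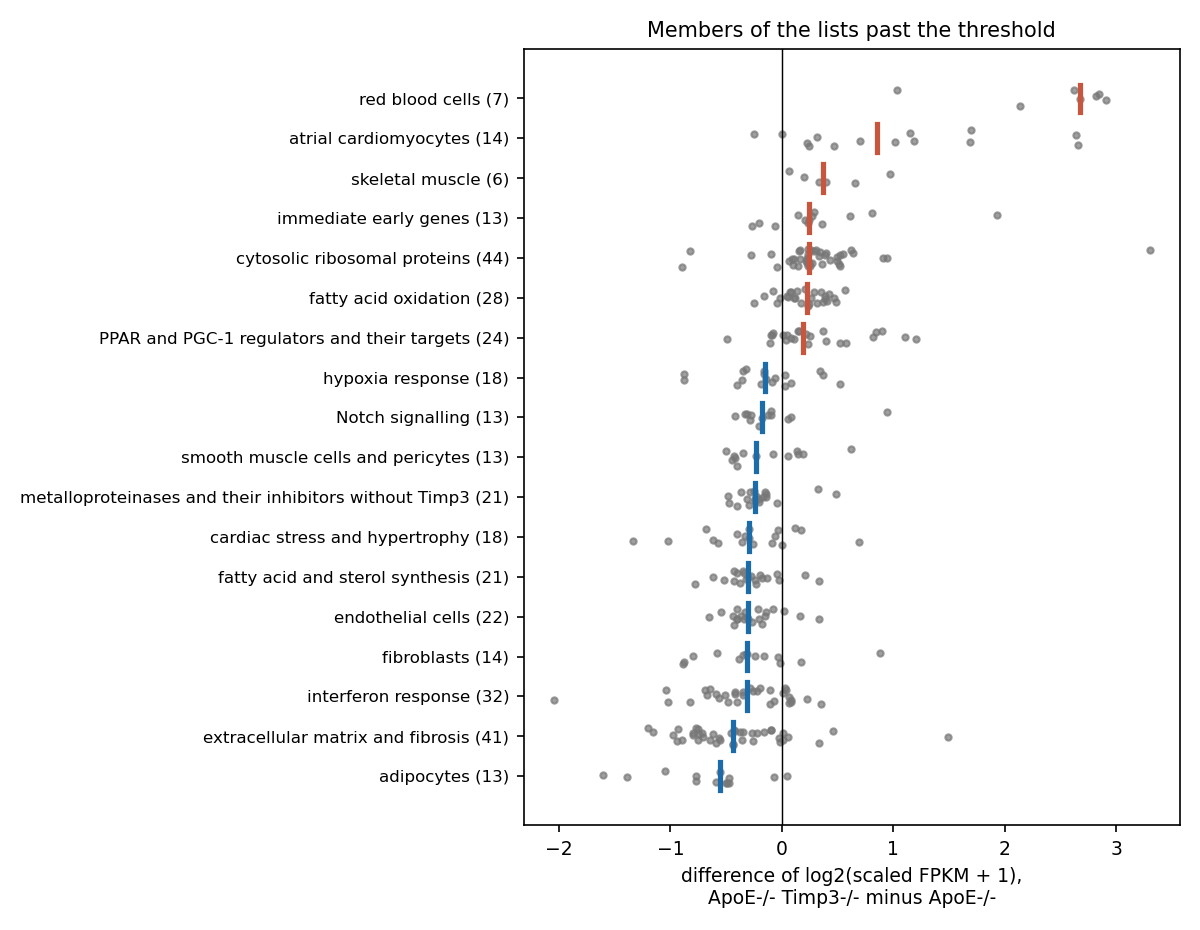
Log2 differences between genotypes (horizontal axis, double mutants minus controls, of scaled FPKM + 1) of the tested genes in the 18 lists that passed camera, with the number of tested genes in brackets. Points are genes and vertical bars the list medians, red above 0 and blue below; the medians run from -0.56 in adipocytes to 2.68 in red blood cells.

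Genes next to Timp3 were not changed more often than genes elsewhere. Within 20 Mb of Timp3, 8 of 228 tested genes had an unadjusted p under 0.01, against 416 of 11156 other genes, an odds ratio of 0.94 (95% interval 0.40 to 1.90; Fisher's exact test, p = 1). Of these 228 genes, 0 passed limma's adjusted threshold, and 5 passed with libraries weighted by their spread. The odds ratio was 0.62 without library 2, 1.66 without library 4 and 1.55 without library 5. The 5 with the smallest p were 2 genes without a symbol, Rassf9, 1190007I07Rik and Tle6. Rassf9, an endosomal trafficking gene, was at 2.21 ± 0.105 against 0.850 ± 0.134, 1190007I07Rik at 4.28 ± 0.636 against 2.07 ± 0.383 and Tle6, a transcriptional corepressor, at 1.86 ± 0.103 against 2.95 ± 0.0731. The genes without a symbol, ENSMUSG00000074856 and ENSMUSG00000074859, were at 2.72 ± 0.329 against 5.39 ± 0.377 and at 5.56 ± 0.816 against 10.2 ± 1.72.

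At the level of single transcripts, 17 of 12699 passed limma's test, 5 higher and 12 lower in the double mutants. All 17 were listed at 0 in every library of one genotype, and 0 belonged to a gene past the gene threshold. Such a pattern was not particular to genotype. By genotype, 61 tested transcripts were at 0 on one side and above 0 throughout the other. In other splits of the libraries into 3 and 3 there were 34 to 87. A transcript of Hadhb, a subunit of the trifunctional protein of fatty acid oxidation, had the smallest p and was chosen after its values were seen: it was listed at 0 in the controls and at 69.8, 49.98 and 64.9 in libraries 4, 5 and 6 (adjusted p = 8.9e-05). The files divide a gene's reads among transcripts, so a 0 for one transcript need not be a 0 for its gene. The count was 2 with a filter at 5 FPKM, and 53, 41, 53, 35 and 39 without library 1, 2, 4, 5 and 6.

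The libraries did not separate by genotype first. Pearson correlations over the tested genes were 0.934 to 0.962 within the controls, 0.947 to 0.970 within the double mutants and 0.925 to 0.953 between them. The first principal component of the 500 most variable genes held 33.5% of the variance and parted libraries 1, 5 and 6 (at -25.1, -7.38 and -6.58) from libraries 2, 3 and 4 (at 15.7, 6.83 and 16.5). The second, with 22.6%, separated the genotypes, with the controls between -12.7 and -10.2 and the double mutants between 7.77 and 16.1. The share of these genes' variance that lay between the genotypes was 22.2%, and 32.2%, 27.9% and 28.2% without library 1, 2 and 4. With fewer libraries any split takes a larger share on average, so these values do not show a stronger separation than the 22.2%. In the 9 other splits of all libraries into 3 and 3 the share ran from 15.6% to 30.7%, a range that holds the 22.2% of the genotypes. The highest was that of libraries 1, 5 and 6 against 2, 3 and 4. All 6 libraries carried Xist, the transcript of the inactive X chromosome, at 3.31 to 9.92 FPKM, and the Y-linked genes were listed at 0 in all 6. The listed values of these genes showed no difference in sex between the groups, although a listed 0 is not proof of absent RNA. Most of the Xist signal was in assembled transcripts: with reference transcripts alone it exceeded 1 FPKM in 1 library.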

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

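The alternatives chosen only after the result was seen were reference transcripts alone, coverage in place of FPKM, stricter assignment, removal of the length trend and leaving out genes at 0. In no run did Timp3 pass limma's threshold, with log2 differences from -0.79 to -0.45 over the settings and -0.73 to -0.41 with 1 library left out. The 5 genes past the threshold became 3 with a pseudocount of 0.1 (3 shared), 1 with a pseudocount of 10 (1 shared), 1 at a filter of 5 FPKM (1 shared), 4 with the strongest transcript (0 higher, 4 lower, 0 shared), 7 with reference transcripts (2 higher, 5 lower, 3 shared), 9 with no filter (5 shared), 104 with library weights (60 higher, 44 lower, 5 shared), 8 with voom (5 shared), 8 with coverage (4 shared) and 0 without genes at 0. Leaving out 1 library gave 3 to 11, with 2 to 5 shared. Scaling to a fixed total gave 7, with 3 higher and 4 lower, and removal of the length trend 4, with 3 higher and 1 lower. The 18 lists became 0 with an estimated correlation, 0 by fry, 9 with library weights, 11 at 5 FPKM, 11 with the strongest transcript and 10 with reference transcripts, and 13 to 16 with 1 library left out. Scaling to a fixed total gave 13, with 7 higher and 6 lower, and removal of the length trend 16, with 8 higher and 8 lower. Transcripts fell to 2 at a filter of 5 FPKM and ranged from 21 to 53 with 1 library left out. With 1 library left out, the share of variance between genotypes ranged from 24.0% to 32.2%, where fewer libraries raise the share of any split. The odds ratio near Timp3 ranged from 0.62 to 1.66 with 1 library left out. Libraries with Xist above 1 FPKM and Y-linked genes at 0 were 6, and 1 with reference transcripts alone. Fewer genes entered the test under the stricter filters and without genes at 0; for the other changes the cause was not tested.

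Of the named genes, 4 changed direction: Cyp51 at 0.20 with reference transcripts and 0.20 with the strongest transcript, Srebf2 at 0.025 and 0.017, Rcan1 at 0.033 with the strongest transcript and Myh4 at -0.19 with reference transcripts. List medians that turned were mostly near 0. As deposited, calcium handling was at -0.050, glycolysis at -0.052 and the respiratory chain at -0.024. Under quantile normalization the values were -0.044, -0.084 and -0.12 (the last a call downward, adjusted p = 6.8e-04), with heat shock at -0.0067, tricarboxylic acid cycle at -0.069 and the growth factor family at 0.0063. Scaling to a fixed total gave -0.13, -0.16 and -0.14, with heat shock at -0.061 and the tricarboxylic acid cycle at -0.099; it moves the median of all genes below 0. Library weights gave calcium handling -0.022, glycolysis -0.053, the respiratory chain -0.031, adipocytes 0.075, fatty acid uptake 0.048, macrophages 0.17 and unfolded protein 0.055. Macrophages were at 0.036 with coverage, 0.012 with no filter, 0.028 with reference transcripts and 0.094 with voom. Reference transcripts gave calcium handling -0.051, and the strongest transcript gave it -0.060 and TNF responses 0.039. The filter at 5 FPKM gave glycolysis -0.018, removal of the length trend gave the respiratory chain -0.047, and no filter gave the apelin list 0.0055. With 1 library left out, medians ranged from -0.048 to 0.059 for fatty acid uptake, -0.023 to 0.094 for glycolysis, -0.086 to 0.16 for the respiratory chain, -0.11 to 0.090 for calcium handling, -0.23 to 0.32 for macrophages, -1.31 to 0.14 for adipocytes, -0.17 to 0.032 for the growth factor family and -0.017 to 0.033 for unfolded protein. The cause was not tested. Apart from single libraries, 14 results of named genes lost their call, 14 gained one and 6 turned direction. Only 5 genes were past the threshold in the main fit, so most named genes had no call to lose. Of the list results, 467 kept direction and side of the threshold, 85 lost their call, 9 gained one and 31 turned direction.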

Other observations

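Tests chosen only after the result was seen were those of overlapping transcripts and of the cardiomyocyte share, and the count of splits for genes. The comparison of Aplnr and Apln with endothelial markers was corrected after a first run was seen, by centring the markers' mean, which left the differences unchanged and narrowed their intervals; that of Apln held 0 before and no longer did. Circadian clock genes were higher in part. Cry2, a repressor of the clock, was at a scaled FPKM of 8.99 ± 0.772 in the controls and 13.2 ± 0.844 in the double mutants (SD, n = 3 each). Per2, another repressor, was at 3.89 ± 0.674 against 8.50 ± 3.58 and Hlf, a clock output gene, at 4.86 ± 1.29 against 8.53 ± 0.913. These 3 passed upward when adjusted over the list alone, at log2 differences of 0.50, 0.90 and 0.72, and 0 passed over all genes by limma, with 5 higher and 1 lower at an unadjusted p under 0.05. Cry1 was at 1.44 ± 0.103 against 2.31 ± 0.613. The list of 16 tested genes had a median of 0.31 and a mean of 0.09 and did not pass camera (adjusted p = 0.16, and 0.58 with an estimated correlation); it passed with voom, at a median of 0.34, and without library 3, at 0.32, and without library 2 the median was 0.07. The hour at which the hearts were taken is not given in the sources used here.

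The 5 genes past the threshold were listed at 0 in a whole genotype, and 3 explanations were weighed. Estimates that failed regardless of genotype would give as many such genes in other splits: 7 tested genes were at 0 on one side and above 0 on the other by genotype, against at most 5 in the 9 other splits, which are too few to decide. Reads given to an overlapping transcript are argued against as the cause for the set, since only 2 of the 5 (Trim12a and Wdfy1) had such transcripts at a level like the gene's. For Wdfy1 that level came from library 2 alone. In libraries 1 and 3 Wdfy1 and the overlapping Mrpl44 were both listed at 0, which failed estimates at that place could give and overlap could not. Overlap stays open for Wdfy1 in library 2 and for Trim12a. The transcripts over Trim12a were not higher where it was at 0 (mean FPKM 5.62 against 6.44). A chromosome segment of another strain was looked for within 5 Mb, where the odds ratio of an unadjusted p under 0.01 was 1.00 (95% interval 0.51 to 1.80; Fisher's exact test), which leaves it open. An effect of Timp3 loss stays untested.

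The lower matrix genes may come from fewer cells that make them or from less made per cell. Transcript length is argued against, since 0% of 10000 random lists matched on length and level had a median as low (95% of them between -0.10 and 0.06, against -0.44). A larger share of cardiomyocytes, which would lower all other cell types alike, stays open: the macrophage median lay 0.39 above the matrix median (95% interval over genes 0.25 to 0.65), but per library the difference of the list means overlapped between genotypes (deviations of 0.51, -0.59 and -0.45 in the controls and of 0.10, 0.18 and 0.26 in the double mutants). Fewer fibroblasts stay open: 11 fibroblast markers outside the matrix list had a median of -0.31, which differed from the matrix median by 0.13 (95% interval over genes -0.15 to 0.48). An effect of genotype on matrix expression within cells was not tested.

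Low Aplnr could come from fewer endothelial cells, in which the receptor gene is expressed. The mean of the 22 endothelial markers differed by -0.26. Relative to it, Aplnr still differed by -1.25 between genotypes (95% interval -1.77 to -0.73). This argues against an even loss of endothelial cells as the whole cause. The mean of general markers cannot show a loss confined to the cells that express Aplnr, so that stays open. For Apln the relative difference was -0.62 (95% interval -1.09 to -0.16), with no prediction written for it, and it rests on that correction. A lower level per cell, linked to the genotype, remains a hypothesis, since Aplnr did not pass the test over all genes.

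The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The genotypes gave 5 genes, and 2 of the 10 splits gave as many, with 13 the highest of the others. For lists 1 split, the genotypes, reached 18, with 15 the highest of the others. For transcripts 3 splits reached the 17 of the genotypes, with 46 the highest of the others. For the odds ratio near Timp3 of 0.94, 4 splits were as high, with 5.47 the highest of the others. The split with 13 genes set libraries 1, 5 and 6 against 2, 3 and 4. It gave 46 transcripts past the threshold and 1222 genes at an unadjusted p under 0.05 by limma. It parted the libraries as Myl7 and the mean of the atrial list did. Nppa, a gene of that list, was not parted so. It was listed at 823, 802 and 104 in libraries 1, 2 and 3 and at 142, 491 and 852 in libraries 4, 5 and 6. The split points to a structure of the samples beside genotype, noticed after the atrial values were seen. Near Apoe, which was targeted in both groups, 7 of 254 genes within 20 Mb had an unadjusted p under 0.01. The odds ratio was 0.73 (95% interval 0.29 to 1.54). Of these genes, Zfp30 and Blvrb had the smallest p. Zfp30 was listed at 1.91, 1.56 and 1.06 in libraries 1 to 3 and at 4.62, 4.08 and 4.42 in libraries 4 to 6. Blvrb was listed at 4.45, 3.72 and 3.92 against 12.0, 7.37 and 10.7. Their adjusted p by limma was 0.056 and 0.10. Mrps12 was lower, at a log2 difference of -0.88. A chromosome segment differing there between the groups stays open.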
